A study of Mus musculus with 20 samples.

How the data were processed

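Single-cell RNA was measured in cells from mouse dorsal skin epidermis during anagen, the growth phase of the hair cycle. The labels list 4 samples of control mice, which carried the Nfatc1-CreER driver with the R26R and mTmG reporters, and 16 samples of mice with the same transgenes that were also Fgf5-/-. Nfatc1-CreER is a recombinase switched on by tamoxifen in cells that express Nfatc1, among them hair follicle bulge stem cells, and mTmG is a reporter that changes from a red to a green membrane protein in recombined cells. Per the labels, tamoxifen was given for 3 days from postnatal day 21 or 22 in the control group and from postnatal day 23 or 24 in the mutant group, so the start of treatment differs with genotype, and the labels give no age at harvest. The labels do not say which samples are separate animals, and all samples of a group were deposited in 1 matrix whose barcodes carry a single library suffix. Each group therefore counts as 1 sample, nothing was tested between groups, and no p-value was computed.

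The deposited values are raw UMI counts per gene and barcode from 10x Genomics 3' v3 libraries. Counting was done with Cell Ranger 3.0.2, per the file headers, and Seurat 3.0.0 and 3.1.0 and the GRCm38 (mm10) build are named in the submitters' processing notes. The gene table in the deposited files adds the tomato and eGFP reporter sequences to the mouse genes, 31055 features in all. The control matrix held 16973 barcodes with 140880809 UMIs (median 4763 per barcode) and the mutant matrix 13411 barcodes with 97817173 UMIs (median 5153), and the lowest total was 500 UMIs in both. Gene coordinates are those of the GENCODE vM21 annotation of GRCm38.

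Barcodes with at least 500 detected genes and at most 15% mitochondrial UMIs were kept, which removed 2430 control and 1396 mutant barcodes for few genes and a further 387 and 560 for mitochondrial UMIs. Scrublet (scanpy 1.11.5) was run on each library and its calls were removed, 457 control cells (3.23%) and 455 mutant cells (3.97%). The 13699 control and 11000 mutant cells left were scaled to 10000 counts per cell and log-transformed. The 2000 most variable genes, without cell cycle and X- or Y-linked list genes, gave 30 principal components (scikit-learn 1.9.0), 15 nearest neighbours and Leiden clusters at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with both libraries together and no batch integration. Clusters were scored with marker sets of 29 cell types. A cluster took the name "X-like" only if its best set scored at least 1 and led the next by 0.3, with at least 3 detected markers, and if its 10 leading genes did not hold more markers of another type. All other clusters keep their number. Classes with at least 200 cells in each library, 14 in all, were compared.

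UMIs were summed per class and library and divided by the class total, which gives CPM. Ratios are log2 of mutant over control with exact conditional 95% intervals for 2 Poisson counts. Levels carry exact Poisson intervals, and shares of cells carry exact Clopper-Pearson intervals (scipy 1.17.1). Ratios of shares carry the first kind of interval, which is too wide where shares are high. All intervals cover counting error only, and there are no replicates behind any value. A ratio is called large if it is at least 2-fold, with the nearer bound beyond 1.5-fold and at least 100 CPM in the higher library, and the words rose, fell and changed are kept for large ratios and for lists outside their random range. Named are the 10 largest ratios in each direction for the 4 classes with most cells and 5 in each direction for the others. Possible free RNA (under 10% of the gene's highest class), mitochondrial and ribosomal genes and unnamed gene models were counted only. Up to 10 genes with large ratios in the most classes, Fgf5, its receptors, Nfatc1 and up to 4 members of each gene list are named as well. Genes named outside these rules were chosen after their values were seen.

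The 29 gene lists covered signalling pathways, the cell cycle, keratin groups, matrix, metabolism, stress responses and sex-linked genes. For each class with at least 4 members at 10 or more CPM, the median log2 ratio (0.5 counts added to each sum) was set against 10000 random lists of the same size matched on expression in 20 bins, and it is called outside if it lay below the 2.5 or above the 97.5 percentile. For shares of cells with at least 2 UMIs of the S phase or G2/M list, each cell was thinned to 1500 UMIs and shallower cells were left out. The cell filters, markers, lists, size rule and most alternative settings were fixed before the data were examined. Where leading genes of a class had large ratios, its size was read only from a second clustering formed without the 1170 genes with a large ratio in any class, which was added after the data were seen.

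Alternatives covered stricter filters, doublets kept, resolutions 0.5 and 2, separate clustering of each library, thinned cells, other level minimums, means over cells, equal weight of a class's clusters, and scaling with edgeR 4.0.16 TMM or DESeq2 1.42.0 median-of-ratios factors (R 4.3.3), which were used for factors only. Near-identical copies of named genes were searched with BLAST 2.17.0 over the last 500 bases of annotated transcripts (80 bases at 95% identity). Other tools were numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and Python 3.11.15. The steps were tested on simulated counts for cluster 0, interfollicular basal and dermal papilla-like cells over 31055 genes with 200 changed. In each of the 3 classes the size rule called 0% of genes simulated at 1.5-fold and 100% of those at 2.5-fold and at 4-fold, with 0 false calls. The simulated counts held counting error only. They had no variation between animals, libraries or clusterings, so these rates do not give the false calls to be expected in the real libraries. Intervals of unchanged genes held the true value for 93.1% of genes in cluster 0, 78.9% in interfollicular basal cells, where changed abundant genes moved the class total by 0.04 log2, and 95.6% in dermal papilla-like cells. Of simulated unchanged lists, 5%, 3% and 7% lay outside the random range in the same order, and of lists moved by 0.5 log2, 100% did. Those lists were randomly drawn genes, so lists whose members vary together were not covered.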

Results

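Anagen dorsal skin of control mice and of Fgf5-/- mice was compared cell by cell. Fgf5 encodes a secreted fibroblast growth factor known to promote the end of anagen, so the comparison addresses how the cell makeup and gene expression of growing skin differ without it. The control group had 4 listed samples pooled in 1 matrix of 16973 barcodes, and the mutant group 16 listed samples pooled in 1 matrix of 13411 barcodes. After filtering, 13699 control cells with 129448096 UMIs (median 5579 per cell) and 11000 mutant cells with 87651183 UMIs (median 5990) were analysed. Over all barcodes before filtering, mitochondrial transcripts made up 3.56% of control and 5.81% of mutant UMIs, and the kept cells had medians of 3.21% and 4.92%. With 1 pooled matrix per group there were no replicates, all differences below are between these matrices, and the mutant mice started tamoxifen about 2 days later than the controls.

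Fgf5 (ENSMUSG00000029337, chromosome 5, 98254184 to 98277030, plus strand, GRCm38) still gave transcripts in the mutant library. It had 1563 UMIs in control cells, 12.1 CPM (UMI counts scaled to a common total, 95% interval 11.5 to 12.7), and 811 UMIs in mutant cells, 9.25 CPM (8.63 to 9.91). Among the compared classes and cluster 18, the level was highest in cluster 18, which had Fgf5 among its leading genes. Cluster 18 carried outer root sheath and bulge markers without a clear lead of either. There, 63.8% of 362 control cells and 64.0% of 125 mutant cells held an Fgf5 UMI, at 198 and 277 CPM (log2 ratio 0.49, 0.24 to 0.73). Cluster 0, whose best marker set was that of the outer root sheath, the outer sleeve of the follicle, had 22.0 and 10.9 CPM (log2 ratio -1.01, -1.49 to -0.56). Cluster 2, which was led by the histone gene Hist1h1b and in which no marker set stood out, had 41.3 and 24.4 CPM (-0.76, -1.02 to -0.50). In T cell or NK cell-like cells, which should lack Fgf5, 0.476% of control cells and 0% of mutant cells held a UMI at median depths of 2355 and 2061 UMIs. The labels do not describe the mutant allele, so the 3' tags counted here check nothing about genotype.

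**Figure D1:**
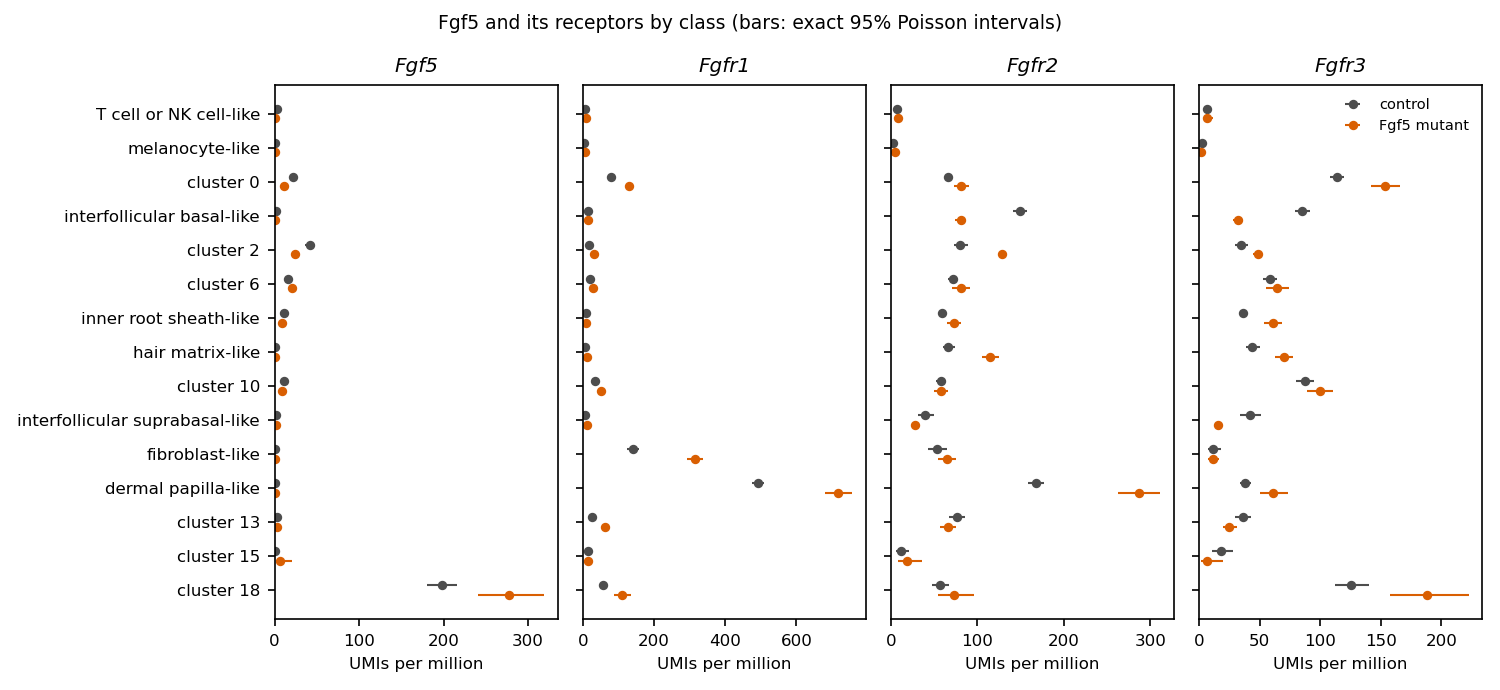
CPM of Fgf5 and of 3 FGF receptor genes (x axes) in each compared class and in cluster 18 (y axis), with exact 95% Poisson intervals, for the control (grey) and mutant (orange) libraries. Fgf5 stands highest in cluster 18 in both libraries, at 198 and 277 CPM.

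The FGF receptor genes differed between libraries by cell class. Fgfr1 (ENSMUSG00000031565, chromosome 8, 25513654 to 25575718), the main receptor of FGF5, was level over all cells, 52.5 CPM in both libraries. It was highest in dermal papilla-like cells, the mesenchymal signalling centre at the follicle base, at 493 and 718 CPM (log2 ratio 0.54), and it rose in fibroblast-like cells from 141 to 314 CPM (1.16, 0.95 to 1.37). Fgfr2 (ENSMUSG00000030849), the receptor through which FGF7 and FGF10 act on keratinocytes, had 149 and 80.7 CPM in interfollicular basal cells (-0.89, -1.03 to -0.75), and 66.4 and 114.8 CPM in hair matrix-like cells (0.79). Fgfr3 (ENSMUSG00000054252) had 85.2 and 31.8 CPM in interfollicular basal cells (-1.42, -1.63 to -1.21) and 114 and 153 CPM in cluster 0 (0.43), and all of these stayed below the size rule. Fgfr4 was found almost only in fibroblast-like cells, at 37.7 and 38.7 CPM. Among ligands of dermal papilla-like cells, Fgf7 had 786 and 677 CPM and Fgf10 441 and 297 (-0.57), also below the size rule.

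Cell shares were compared directly for the 4 classes whose leading genes had no large ratios. Cluster 0 made up 13.6% of control cells and 6.60% of mutant cells (log2 ratio -1.04, -1.17 to -0.92). Inner root sheath-like cells, which mould the growing hair and were led by Tchh, Krt71 and Krt25, made up 6.18% and 2.67% (-1.21, -1.41 to -1.02). Cluster 6, led by the proliferation genes Mki67, Pclaf and Stmn1, made up 5.93% and 3.32% (-0.84). It was not found again at resolution 0.5, with thinned cells or with each library clustered on its own. Cluster 2, which like cluster 6 had Hist1h1b among its leading genes, went the other way, 2.81% and 12.7%, though some of its leading genes had large ratios. Cluster 10, led by Pthlh, Krt6a and Sox9 with a tie of outer root sheath and companion layer markers, made up 4.31% and 3.39% (-0.34, -0.54 to -0.16), a difference that turned to 0.09 when each library was clustered on its own.

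For the other classes, sizes came from the clustering formed without genes of large ratio, called the second clustering below. In it, interfollicular basal keratinocyte-like cells, the stem and progenitor layer of the epidermis, made up 6.53% of control and 11.4% of mutant cells (log2 ratio 0.80, 0.68 to 0.93). Interfollicular suprabasal keratinocyte-like cells, their differentiating progeny, made up 1.56% and 4.44% (1.51), upper follicle keratinocyte-like cells 2.44% and 4.41% (0.85), melanocyte-like cells 8.13% and 11.6% (0.51) and fibroblast-like cells 2.53% and 3.81% (0.59). Hair matrix-like cells, the dividing source of the hair shaft, made up 3.99% and 5.19% (0.38, 0.21 to 0.55), dermal papilla-like cells 3.68% and 3.03% (-0.28, -0.49 to -0.08), and inner root sheath-like cells 6.98% and 4.06% (-0.78). T cell or NK cell-like cells made up 14.5% and 10.1% (-0.52, or -1.81 with the strict filter and -1.11 with each library clustered on its own), and an unnamed cluster with T cell markers a further 7.38% and 1.81% (-2.03). An unnamed cluster led by Hist1h1b, Pclaf and Stmn1, genes that also led cluster 6, made up 8.18% and 14.8% (0.85). By shared cells this unnamed cluster matched cluster 2, and cluster 6 itself was not found again in this clustering. The match to cluster 2 gave 0.90 at resolution 0.5 and 0.89 with thinned cells, where cluster 6 was not found either. The -0.84 of cluster 6 thus held only where its cells formed a cluster of their own. It gives no direction for dividing cells as a whole. Medulla-like cells made up 1.23% and 2.72% (1.14). The largest difference was in an unnamed cluster whose 2 best marker sets were those of T cells or NK cells and of interfollicular basal cells, 1.66% and 0.164% (-3.35). Its median depth was 10861.5 UMIs, against 2239 and 4827.5 in the largest clusters of those 2 types, and Scrublet had called 3.23% and 3.97% of cells as doublets where 11.3% and 9.16% were expected. A cluster led by Krt6a and Apoe had 1.83% and 0.909% (-1.01). How skin was dissociated can set such shares, and the labels give no sort or yield.

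**Figure D2:**
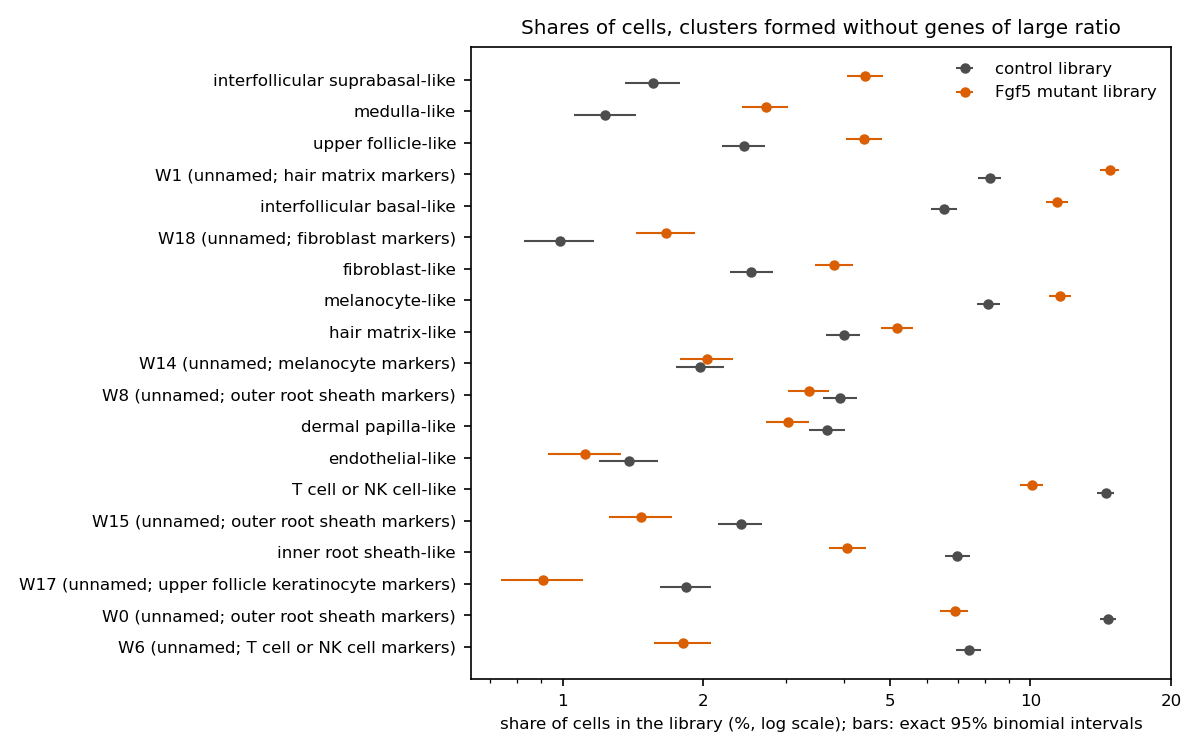
Share of cells of each library (x axis, percent, log scale) in the classes of the clustering formed without genes of large ratio (y axis), with exact 95% binomial intervals, and unnamed clusters of that clustering marked W. Interfollicular basal-like cells stand at 6.53% in the control and 11.4% in the mutant library, inner root sheath-like cells at 6.98% and 4.06%.

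Expression was then compared within the 14 classes. Large ratios were found 964 times in the higher and 980 times in the lower direction, over 1170 genes, of which 807 had one in a single class. TMM factors gave 1403 and 793 and DESeq2 factors 1412 and 780, and 142 of the large ratios were marked as possible free RNA. Interfollicular basal, suprabasal and dermal papilla-like cells had the largest shares of compared genes past the size rule, 19.7%, 19.1% and 17.7%, and cluster 6 the smallest, 1.88%. Some named genes share near-identical 3' ends with other annotated genes or pseudogenes, so their values are uncertain: Krt16, Hmgn2, Erh, Stmn1, Pclaf, Cks2, Fdps, Idi1, Gstp1, H2-K1, Wdr89, Csnk2a1, Mmp3, Krt27, Selenbp1, Cenpf, Ube2c, Spata7, Adam15, Samd11 and Ftl1-ps1.

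Interfollicular basal keratinocyte-like cells of the mutant library showed higher levels of Ccl20, Tslp and wound genes and lower levels of immediate early and division genes. Ccl20 (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167), a chemokine that draws CCR6-bearing lymphocytes, rose from 31.5 to 1310 CPM (log2 ratio 5.38, 5.20 to 5.57). Tslp (chromosome 18, 32815383 to 32819797), an epithelial cytokine of type 2 immunity, rose from 513 to 3804 CPM (2.89), Krt16, a keratin of wounded and stressed epidermis, from 337 to 2748 (3.03), and Epgn, an EGF receptor ligand, from 327 to 1930 (2.56). Slc6a14 (3.00), an amino acid transporter, Ch25h (2.84), a cholesterol hydroxylase, the protease gene Adam8 (2.49), the coagulation factor gene F3 (2.41) and the transcription factor gene Tead1 (2.40) also rose. Txnip, a thioredoxin inhibitor that limits glucose uptake, fell from 200 to 11.4 CPM (-4.12), the immediate early genes Nr4a1 and Fos fell from 642 to 56.3 (-3.51) and from 1554 to 165 (-3.24), and Socs3, a feedback inhibitor of cytokine signalling, fell from 396 to 40.9 (-3.27). Capns2 (-3.51), a calpain subunit, the cell cycle inhibitor gene Cdkn2d (-3.32), the mitosis genes Cenpf (-3.25) and Ube2c (-2.91), the BMP target Id1 (-3.01) and Gadd45g (-2.71) fell as well. Upper follicle markers had a median log2 ratio of 1.04 in this class, with Plet1 at 320 and 1389 CPM (2.12), Cst6 at 1.35, Krt79 at -0.02 and Lrig1 at -1.43.

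In this class 153 genes had large higher and 160 large lower ratios among 1592 compared. TMM factors, which moved the median by 0.29, gave 264 and 93, and DESeq2 factors (0.28) gave 258 and 95. The control cells lay in cluster 9 (924 of 943 cells) and the mutant cells in cluster 5 (1174 of 1214), and Tslp and Ccl20 were among the leading genes of cluster 5. In the clustering formed without genes of large ratio these cells formed 1 cluster, of 894 control and 1254 mutant cells. All 20 genes that the naming rule gave kept large ratios there, among them Ccl20 at 5.36, Tslp at 2.83, Fos at -3.38 and Txnip at -4.55. With cell numbers so close to the 943 and 1214 first summed, these values do not test the split between clusters 5 and 9. With both original clusters weighted equally, 93 genes passed the rule and Tslp, Socs3, Cenpf and Id1 had ratios of -0.07, 0.31, 0.13 and 0.03, values that rest on 19 control cells of cluster 5 and 40 mutant cells of cluster 9.

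**Figure D3:**
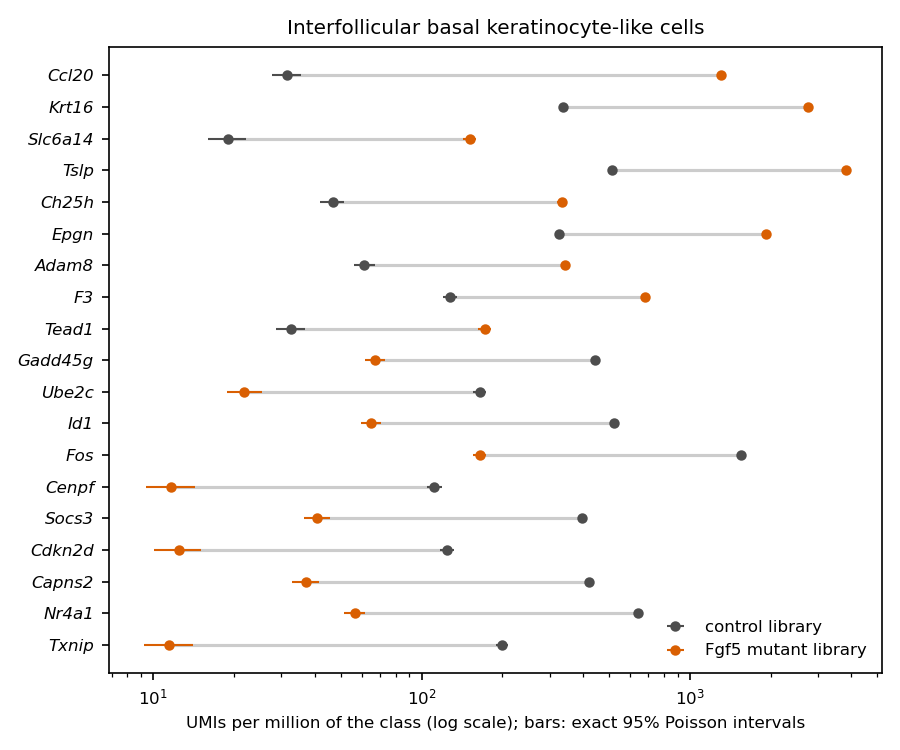
CPM (x axis, log scale) of named genes in interfollicular basal keratinocyte-like cells (y axis), with exact 95% Poisson intervals, for the control (grey) and mutant (orange) libraries. Ccl20 runs from 31.5 to 1310 CPM and Txnip from 200 to 11.4.

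The suprabasal keratinocyte-like cells of the mutant library had higher levels of several Sprr2 genes and of Krt16, while the epidermal differentiation list lay within its random range (median 0.21). Sprr2f (22.5 to 509 CPM, log2 ratio 4.48), Sprr2h (3.79) and Sprr2d (3.58), small proline-rich proteins of the cornified envelope, the kallikrein gene Klk9 (4.06) and Krt16 (516 to 5437 CPM, 3.40) rose. Gadd45g (-3.93), Rgcc (-3.72), Fos (-3.53), Nr4a1 (-3.40) and Txnip (-3.32) fell. Here 155 genes had large higher and 152 large lower ratios, against 378 and 64 with TMM factors (median shift 0.43) and 375 and 64 with DESeq2 factors (0.42).

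Cluster 13, which held upper follicle and sebaceous gland markers in a tie, had higher Serpinb2 (159 to 796 CPM, 2.33), Ccl20 (2.31), Krt16 (1.98) and Hivep3 (1.97) in the mutant library. Elovl4 (317 to 16.8 CPM, -4.23) and Elovl3 (-3.53), which lengthen fatty acids, Fa2h (-3.44), which hydroxylates them, Akr1c18 (-3.47), a steroid dehydrogenase, and Paqr7 (-4.67), a progesterone receptor, fell. The higher and lower counts were 90 and 111, against 119 and 87 with TMM factors (0.11) and 112 and 89 with DESeq2 factors. Sebaceous cells could not be separated from upper follicle cells here, so their proportion within cluster 13 is unknown.

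T cell or NK cell-like cells of the mutant library had lower Spp1, Il17a and early response genes. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), the cytokine osteopontin, fell from 311 to 7.33 CPM (log2 ratio -5.37, -6.19 to -4.72), and Il17a, the cytokine of type 17 lymphocytes, from 423 to 50.5 (-3.06). Gadd45b (2115 to 367 CPM, -2.53), Ppp1r15a (-2.35), both induced by stress, the kinase gene Plk3 (-2.62), Rrad (-2.95), Nfkbil1 (-2.92), the phosphatase gene Ptpn6 (-2.66) and Mta3 (-2.47) fell. Cd27, a co-stimulatory receptor, rose from 41.3 to 209 CPM (2.34), the actin crosslinker gene Flna from 101 to 466 (2.21), and the chemokine gene Ccl5 from 107 to 434 (2.02), with Fam71f2 (2.63), St7 (2.59), Yod1 (2.20), Prag1 (2.15), Irf8 (2.03), Foxj1 (2.02) and Ahsa2 (152 CPM in the mutant library). The class had 93 large higher and 115 large lower ratios, against 112 and 99 with TMM factors and 110 and 99 with DESeq2 factors. Its control cells lay mainly in cluster 4 (1309 of 2520) and its mutant cells in cluster 3 (829 of 1039), cluster 14 held 549 and 194, and with the clusters weighted equally 123 genes passed the rule in place of 208. In the clustering formed without genes of large ratio, 18 of the 20 named genes kept large ratios, Spp1 at -5.12, Il17a at -3.43 and Ccl5 at 1.65 among them, while Ptpn6 (-1.46) and Mta3 (-2.14) did not. Cluster 15, where haemoglobin and T cell markers tied, had lower Spp1 (-4.98), Gzmc (-3.95), Gzmb (-3.66) and Samd11 (-3.21) and higher St7 (2.91), Pecam1 (2.84), Adam15 (2.75), Dhx40 (2.62) and Flna (2.54), at a median of only 1541.5 and 1408.5 UMIs per cell.

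Melanocyte-like cells of the mutant library had lower BMP target and sterol genes and lower Mitf and Mc1r. The BMP targets Id3 and Id2, inhibitors of bHLH transcription factors, fell from 555 to 98.7 CPM (-2.49) and from 800 to 267 (-1.58). Mitf, the master regulator of melanocytes, fell from 279 to 101 CPM (-1.47) and Mc1r, the melanocortin receptor, from 332 to 118 (-1.49), while the pigment enzyme genes Dct (11929 and 18607 CPM, 0.64) and Tyrp1 (0.36) stayed below the size rule. The sterol synthesis gene Idi1 (-1.92), the glutathione transferase gene Gstp1 (-2.64, or -2.63 in the second clustering), Gadd45g (-3.18) and Tsc22d1 (-1.46) fell. Tmod1 (1.83), Wdfy1 (1.76), Cnrip1 (1.62), Gsta4 (1.58), the nuclear RNA Neat1 (540 to 1421 CPM, 1.39), Csnk2a1 (1.32), Wdr89 (1.29), Myh9 (1.28), Rgl1 (1.27) and Fam53b (1.21) rose. Large ratios numbered 20 higher and 34 lower, against 40 and 24 with TMM factors (median shift 0.16) and 36 and 25 with DESeq2 factors (0.13).

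In cluster 0, the heat shock genes Hspa1a (422 to 1338 CPM, 1.66), Hspa1b (1.63) and Hsph1 (1.58) rose with Lars2 (1.90), AY036118 (1.86), Wdr89 (1.38), Fam107b (1.22), Pappa (1.05) and Nrg1 (89.6 to 181 CPM, 1.01), a ligand of ERBB receptors. Genes of dividing cells fell, Hmgn2 (-1.88), Pclaf (-1.48), Stmn1 (535 to 219 CPM, -1.29) and Cks2 (-1.25), with Lsm8 (-1.77), Erh (-1.38), the sterol gene Fdps (-1.26), the antigen presentation gene H2-K1 (-1.09) and Hmgn3 (-1.04, or -0.96 in the second clustering). Hopx, a homeodomain protein gene of follicle stem cells and inner bulge cells, fell in cluster 10 (206 to 37.8 CPM, -2.44), cluster 2 (-2.10), hair matrix-like cells (-1.78), inner root sheath-like cells (-1.44) and cluster 6 (-1.26). Slpi, a protease inhibitor, rose in inner root sheath-like cells (1.84, or 2.97 in the second clustering), where the inner root sheath keratin gene Krt26 rose (1.55) and B2m fell (-1.37), though neither kept a large ratio in the clustering formed without such genes (0.95 and -0.74). Hsph1 (2.12) and Hspa1a (1.59) rose and Spata7 (-2.97) fell in hair matrix-like cells, while Neat1 (1.72) and Dusp7 (1.66), a phosphatase of ERK, rose in cluster 10. The counts of large higher and lower ratios were 17 and 22 in cluster 0 (22 and 19 with TMM factors, 23 and 18 without the 50 top genes), 31 and 23 in inner root sheath-like cells (25 and 28 with TMM factors), 25 and 26 in cluster 10, 17 and 20 in hair matrix-like cells, 17 and 17 in cluster 2 and 17 and 11 in cluster 6.

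In dermal papilla-like cells, Ccl2, a monocyte chemokine, rose from 248 to 2159 CPM (log2 ratio 3.12), with Neat1 (3.19), the matrix protein gene Thbs1 (2.99), AY036118 (2.84) and Errfi1 (2.65), a feedback inhibitor of the EGF receptor. The agouti gene, whose product switches melanocytes from black to yellow pigment, fell from 638 to 138 CPM (-2.20), and the lipase gene Lpl (-2.30), Cmtm8 (-2.83) and Gadd45g (-2.37) fell. Of the papilla signals, Edn3 (819 to 341 CPM, -1.26), Rspo4 (-1.21) and Igf1 (364 to 180 CPM, -1.02) fell, while Bmp7 (0.85) and Nog (0.61) stayed below the size rule and the dermal papilla signalling list lay within its random range (-0.22). Fibroblast-like cells had higher Lrrtm3 (145 CPM in the mutant library, 5.08), the prostaglandin synthase gene Ptgs2 (2.97), the cytokine gene Lif (2.97), the matrix protease gene Mmp3 (2.95) and Tnfaip2 (2.74), and lower Id1 (-1.93), Hpgd (-1.91, or -0.88 in the second clustering), an enzyme that degrades prostaglandins, and Tsc22d3 (-1.79), a glucocorticoid target. The inner root sheath keratin gene Krt27 also fell in the fibroblast-like class (-4.41). Dermal papilla-like cells had 185 large higher and 179 large lower ratios (145 and 227 with TMM factors) at median depths of 8542 and 3087 UMIs. Fibroblast-like cells had 72 and 61, against 150 and 27 with TMM factors (median shift 0.24), 177 and 21 with DESeq2 factors (0.29) and 84 and 46 without the 50 top genes.

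Across the 14 classes, with possible free RNA left out, 11 genes had large higher and 7 large lower ratios in 7 or more of them. Rps27rt, a near-identical copy of the ribosomal protein gene Rps27, rose in all 14 (median 1.58), and Gm10076, a near-identical copy of Rpl41, fell in all 14 (-1.84). Wdr89 and AY036118 rose in 13 classes (median log2 ratios 1.38 and 1.74), Neat1 in 10 (0.49 to 3.19 over all classes), Hsph1 in 9 (1.46), and Hspa1b (1.35), Lars2 (1.14) and Myh9 (1.19) in 8 each. AY036118 lies within the span of the gene model Gm42418, which rose in 12 classes (1.47), and the search for copies left out overlapping genes. Gadd45g fell in 10 classes (-1.51) and the stress-induced Ppp1r15a in 8 (-1.14), while Id1 (-1.10), Hmgn2 (-1.45) and Erh (-1.30) fell in 7 each. Ftl1-ps1, a copy of the ferritin light chain gene Ftl1, had ratios of -4.67 to -3.37 over all 14 classes. It fell in melanocyte-like cells from 8904 to 361 CPM (-4.62), where Ftl1 itself had 7670 and 12534 CPM. Ftl1-ps1 is not among the 7 lower genes, because its fall was counted in 6 classes and marked as possible free RNA in the others.

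The gene lists set these genes in context. Of 316 pairs of list and class, 117 lay outside the middle 95% of random lists, 44 higher and 73 lower. The lists were not filtered for possible free RNA. Melanin synthesis genes gave 12 of the 117 and inner root sheath keratins 8, both in fibroblast-like cells too, so the count can include RNA from other cells. BMP targets lay lower in 9 of 14 classes, with medians of -1.44 in melanocyte-like cells (7 of 7 measured members with intervals below 0), -0.96 in interfollicular basal cells and -0.77 in cluster 0. Cholesterol synthesis genes lay lower in 10 of 14 classes, at -1.44 in cluster 13 and at -0.79 in melanocyte-like cells, where Hmgcs1 fell (-1.26). Dissociation stress genes, immediate early genes induced during tissue handling, lay lower in 8 classes, at -1.52 in interfollicular basal cells with 12 of 16 members past the size rule, Ier2 (1433 to 253 CPM) among them, and at -0.93 in T cell or NK cell-like cells, where Atf3 (-2.16) and Egr1 (-1.34) fell. Heat shock genes lay higher in 6 classes and were highest in hair matrix-like cells (0.72), where Hsp90aa1 rose (1.15). Wound and stress keratins and alarmins lay higher in all 5 classes that had 4 measured members, at 1.80 in interfollicular basal cells, where Krt17 rose from 1076 to 4639 CPM (2.11).

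Signalling lists moved less evenly. FGF-ERK feedback targets lay higher in cluster 0 (0.20, 98.1 percentile of random lists) and cluster 10 (0.31) and lower in T cell or NK cell-like cells (-0.92) and cluster 15 (-0.65), and Spry1, an inhibitor of receptor tyrosine kinases, fell in dermal papilla-like cells from 354 to 146 CPM (-1.28). FGF receptors and co-receptors lay higher in clusters 0 (0.29) and 2 (0.45), and the FGF ligand list was measured in 1 class and lay within its random range. Wnt targets lay lower in 3 classes, at -0.57 in melanocyte-like cells (Lef1 at -1.32), Notch targets in 4, at -1.42 in interfollicular basal cells, where Hes1 fell from 169 to 39.0 CPM (-2.11), and Hedgehog targets in cluster 13 (-0.92). TGF-beta targets lay higher in dermal papilla-like cells (0.95), where Ctgf (1.45) and Col1a1 (1.14) rose, and lower in melanocyte-like cells (-0.65, or 0.0841 at a minimum of 1 CPM). Catagen-linked secreted factors lay higher in hair matrix-like cells (0.54), with Bmp2 at 19.8 and 60.4 CPM, and within the random range in the other classes measured, dermal papilla-like cells with a median of 0.62 included, and anagen-linked growth factors lay lower in interfollicular basal cells (-1.42), where Wnt10a fell (-1.08). IGF signalling lay higher in dermal papilla-like cells (0.69), where Irs2 rose (1.35) and Igfbp7 fell (-1.13), in cluster 10 (-0.33 at a minimum of 50 CPM) and in suprabasal cells (-0.41 at a minimum of 1 CPM), and lower in melanocyte-like cells (-0.63). P53 and apoptosis genes lay higher in dermal papilla-like cells (0.68), where Cdkn1a rose to 343 CPM.

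Differentiation lists differed by class too. Epidermal differentiation genes lay higher in 4 classes and lower in 2, with turned direction under another setting in T cell or NK cell-like cells (-1.16), cluster 2 (0.17) and fibroblast-like cells (0.46), and in interfollicular basal cells the median was 0.57 although the early differentiation keratins Krt10 (-2.17) and Krt1 (-1.71) fell. Hair shaft keratins lay lower in hair matrix-like cells (-0.49), in which Krt35 was a leading gene at 3979 and 1837 CPM. Hair differentiation regulators lay higher in suprabasal cells (0.38) and lower in cluster 15 (-0.80), and bulge stem cell genes lay higher in dermal papilla-like cells (0.81) and lower in interfollicular basal cells (-0.95, or 0.0462 at a minimum of 50 CPM), where Sox9 rose (1.75) and Nfib fell (-1.10). Dermal papilla signalling genes lay lower in suprabasal (-1.82) and fibroblast-like cells (-0.57, or 0.17 at a minimum of 50 CPM). Extracellular matrix genes lay higher in 6 classes, at 0.50 in fibroblast-like cells with Col1a1 at 11909 and 22476 CPM (0.92). Interferon response genes lay lower in cluster 10 (-0.71), and hypoxia and glycolysis genes lay within the random range in all 14 classes. Inner root sheath keratins lay lower in 8 classes, fibroblast-like cells included (-3.40), and melanin synthesis genes lay higher in 10 classes and lower in 2 (fibroblast-like cells turned to 0.65 with the strict filter), in libraries where the second clustering put inner root sheath-like cells at 6.98% and 4.06% and melanocyte-like cells at 8.13% and 11.6%. Of the sex-linked list, the X inactivation RNA Xist was at 1465 and 1767 CPM in cluster 0, its antisense partner Tsix was at 10.9 and 64.0, and no Y-linked member reached 10 CPM in any class.

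**Figure D4:**
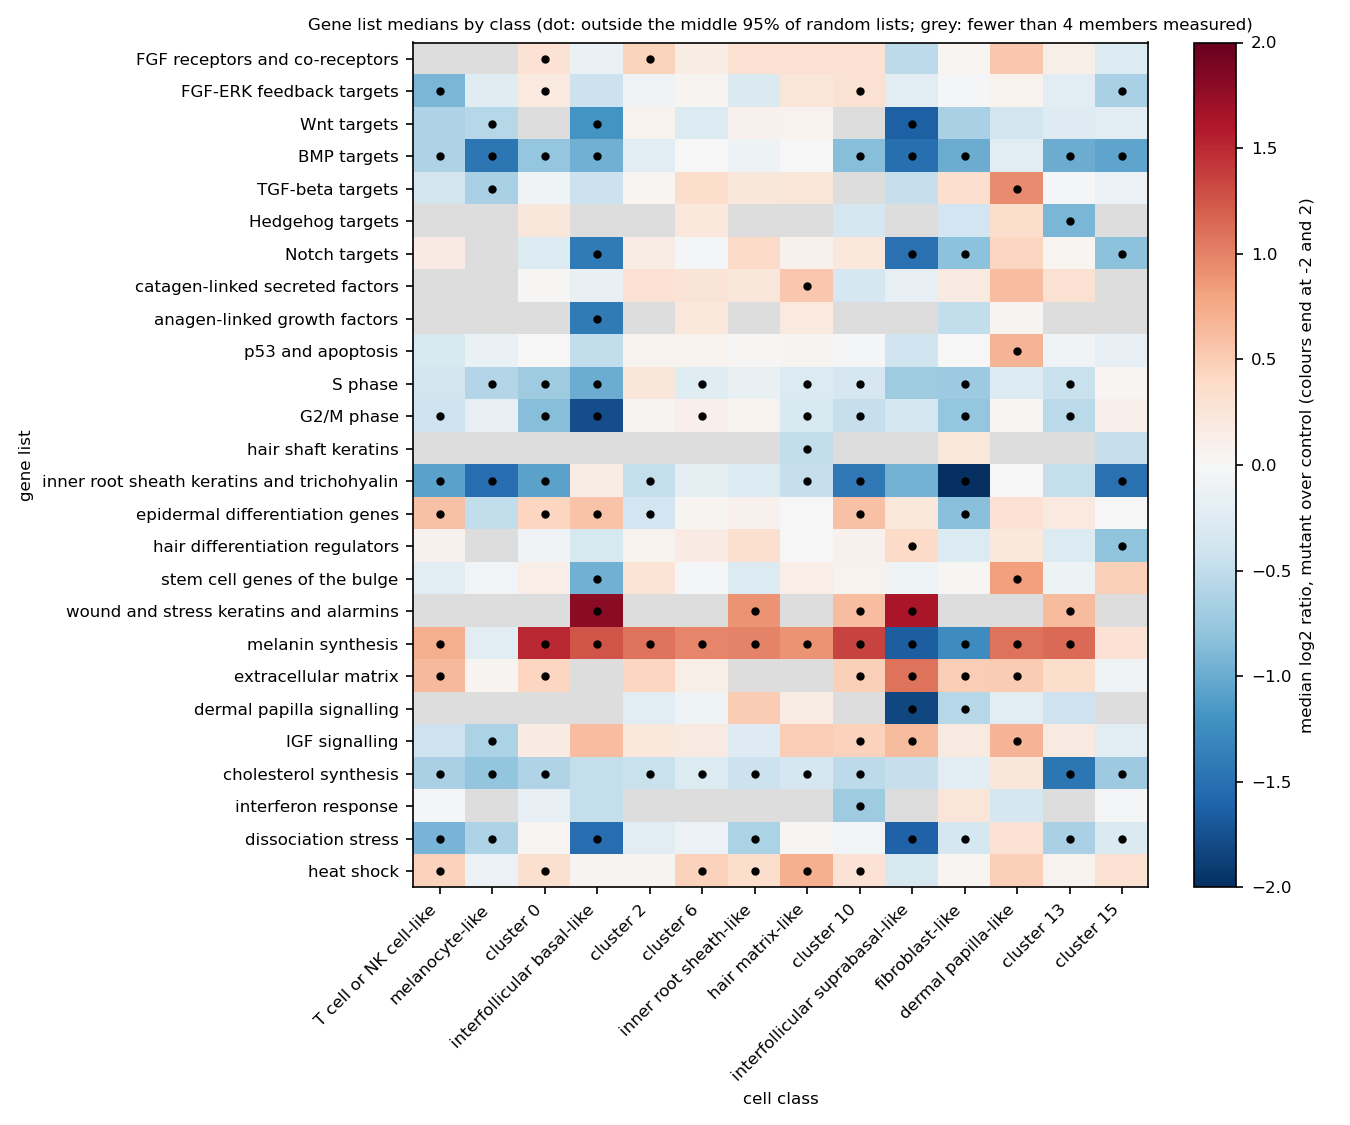
Median log2 ratio of mutant over control (colour) of each gene list (y axis) in each compared class (x axis), with a dot where the median lies outside the middle 95% of random lists. BMP targets lie lower in 9 classes and cholesterol synthesis genes in 10.

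Cell cycle genes were lower in several classes of the mutant library, and not in keratinocytes alone. The S phase list lay lower in 8 classes, with medians of -0.99 in interfollicular basal cells and -0.71 in cluster 0, and the G2/M list lay lower in 7, with -1.78 in interfollicular basal cells and -0.85 in cluster 0, and higher in cluster 6 (0.11, or -0.0111 at a minimum of 50 CPM). After thinning to 1500 UMIs, 48.3% of control cells (46.0 to 50.6%) and 26.6 to 33.5% of mutant cells (95% interval) of cluster 0 held at least 2 UMIs of S phase genes (log2 ratio -0.69, -0.91 to -0.47), against 86.5% and 78.7% without thinning. In interfollicular basal cells these shares were 36.6% and 21.3% (-0.78), against 81.1% and 69.5% without thinning, and in hair matrix-like cells 43.8% and 42.9%. Melanocyte-like cells had 33.4% and 25.7% (-0.38), against 86.1% and 87.8% without thinning. Fibroblast-like cells had 27.8% and 18.4% (-0.59), and T cell or NK cell-like cells 53.9% and 47.4% (-0.19). Dermal papilla-like cells had 29.8% and 39.2% (0.40, 0.02 to 0.77), against 74.6% and 75.1% without thinning, and their S phase list lay within its random range. Thinning left out 50 control and 16 mutant cells of cluster 0, 28 and 7 interfollicular basal cells and 74 and 28 dermal papilla-like cells. In hair cortex or cuticle-like cells, which no longer divide, the S phase shares were 10.1% and 10.7% at median depths of 14410.5 and 12778 UMIs. Their G2/M shares were 46.0% (39.6 to 52.4%) and 34.8% (27.9 to 42.3%), with a log2 ratio of -0.40. The interval of this ratio, -0.87 to 0.06, is too wide for such shares and does not show them level. With shares this high in such cells, 2 or more G2/M UMIs do not mark dividing cells alone. With clusters 0, 2, 6, 10, 18 and 20 pooled, a grouping chosen after the data were seen, 56.8% of control and 51.7% of mutant cells held S phase UMIs (-0.13, -0.23 to -0.04).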

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

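The tests of an equal handling effect and of RNA from other cells over all genes in this part were chosen only after the result was seen. Several results were picked out because the mutant over control ratio went in opposite directions in 2 cell classes, and in each case the difference between the classes was not tested. Fgfr2, the keratinocyte receptor of FGF7 and FGF10, had log2 ratios of -0.89 in interfollicular basal and 0.88 in melanocyte-like cells. Fgfr3 had -1.42 in interfollicular basal and 0.74 in inner root sheath-like cells. Gsta4, a glutathione transferase gene, had -1.15 in dermal papilla-like and 1.58 in melanocyte-like cells, and Hopx had -2.46 in interfollicular basal and 1.84 in T cell or NK cell-like cells. The FGF-ERK feedback list had medians of -0.92 in T cell or NK cell-like cells and 0.31 in cluster 10. The eGFP reporter, which lies outside the compared genes, was picked out because it gave 811 CPM in the mutant library against 745 CPM in the control library.

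In interfollicular basal cells of the mutant library, Ccl20, Tslp and other named genes were higher and immediate early genes such as Fos lower. RNA from other cells stayed undecided: over all 153 genes with large higher ratios the mutant level was 0.818 times the highest level in any other class (median, range 0.00685 to 2.35, 41 genes above every other class), and the 37.4 times found for the 10 named genes against 4 other classes (range 0.951 to 213) decides nothing, because naming had already left out possible free RNA. A shift of the class toward upper follicle cells stayed open, since upper follicle markers had a median log2 ratio of 1.04 over 6 genes, from -1.43 (Lrig1) to 2.12 (Plet1). For the immediate early genes, 1 handling effect of equal size in all cells was argued against, since only 1 of 13 other classes had a median within 0.5 of this one, with a range of -1.61 to 0.29. Handling that acted on some classes more than others, genotype and the later start of tamoxifen were not tested and could each contribute.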

How the results depend on the processing

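The clustering without genes of large ratio was chosen after the data were seen. Of the main results under an alternative, 127 stayed the same, 32 moved and 1 reversed, and of the others 2533 stayed, 529 moved and 19 reversed. The cause was not tested for any of them. Scaling factors move all genes of a class alike and a minimum level moves no ratio, so these could not turn a large ratio. With the mean over cells all 179 named gene values kept their direction and 158 stayed large. Every named value that could be given also kept its direction with the strict filter (149 of 149) and with doublets kept (169 of 169). The same held at resolution 0.5 (109 of 109) and 2 (159 of 159). In the clustering without genes of large ratio 149 of 149 did, of which 138 stayed large. The named genes were chosen for large ratios and largely the same cells were summed again, so these counts are a weak check.

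In the first clustering the log2 ratios of cell shares were -0.96 (T cell or NK cell-like), 0.47 (melanocyte-like), 0.68 (interfollicular basal), 2.18 (cluster 2), -1.21 (inner root sheath-like), -0.34 (cluster 10) and 1.73 (suprabasal), and they moved as follows. With the strict filter, T cell or NK cell-like cells went to -1.81. With each library clustered on its own, T cell or NK cell-like cells went to -1.11, melanocyte-like to 0.72, inner root sheath-like to -1.505, suprabasal to 2.05 and cluster 10 to 0.0873, a reversal. Without genes of large ratio they were -0.52 (T cell or NK cell-like), 0.85 (cluster 2), -0.78 (inner root sheath-like) and 1.51 (suprabasal). At resolution 0.5 interfollicular basal cells went to 6.19 and cluster 2 to 0.90, with thinned cells cluster 2 to 0.89, and inner root sheath-like cells to -0.72 with doublets kept and -0.77 at resolution 2.

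Counts of large ratios followed the minimum level. With none they were 911 in T cell or NK cell-like, 1023 in melanocyte-like, 420 in cluster 0 and 2681 in interfollicular basal cells, and 12834 in all. At 50 CPM they were 341, 119, 71, 580 and 3679. With clusters weighted equally they were 123 in T cell or NK cell-like and 93 in interfollicular basal cells, where Tslp (-0.0706), Socs3 (0.31), Cenpf (0.13) and Id1 (0.0317) reversed. Fgf5 in inner root sheath-like cells went to 0.25 with doublets kept.

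At 50 CPM, 63 pairs of list and class lay outside the random range, and reversals were bulge genes in interfollicular basal cells (0.0462), G2/M in cluster 6 (-0.0111), S phase in hair matrix-like (0.0171), IGF signalling in cluster 10 (-0.33) and dermal papilla signalling in fibroblast-like cells (0.17). At 1 CPM they were TGF-beta targets in melanocyte-like (0.0841), IGF signalling in suprabasal (-0.41) and epidermal differentiation in fibroblast-like cells (0.00934). Epidermal differentiation also reversed in T cell or NK cell-like cells with the strict filter (-1.16) and without genes of large ratio (-0.00753), in cluster 2 without them (0.17) and in fibroblast-like cells with doublets kept (0.46), and melanin synthesis in fibroblast-like cells with the strict filter (0.65).

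The S phase share was lower, with its whole interval below 0, in 8 classes at the main setting of 2 UMIs after thinning. It was so in 4 at 1 UMI or more and in 4 without thinning. The G2/M share was so in 7, 4 and 0 classes in the same order. These intervals are too wide for high shares, so the lower counts at 1 UMI or without thinning do not show that shares were level. Without thinning, G2/M shares were 96.6% and 91.5% in cluster 0 and 96.8% and 90.9% in interfollicular basal cells. In melanocyte-like cells they were 89.5% and 90.3%. Without thinning, melanocyte-like cells stood at 0.0277 (S phase) and 0.0127 (G2/M). There is no value where a class was not found again, chiefly clusters 13 and 15, cluster 6 and suprabasal cells, cluster 2 with each library clustered on its own, and hair matrix-like and interfollicular basal expression at resolution 0.5. No paired analysis was possible because each group was 1 matrix whose barcodes name 1 library, so the planned library block, left-out libraries and tests between libraries were not run. Depth limited shares of cells with a UMI most in cluster 15, at medians of 1541.5 and 1408.5 UMIs.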

Other observations

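The test of clusters 0, 2, 6, 10, 18 and 20 as 1 group was chosen only after the result was seen. Further FGF family genes differed in small cell classes that were not among the 14 compared. Fgf22, an epithelial FGF, had 9.49 CPM in control and 34.2 CPM in mutant hair cortex or cuticle-like cells (log2 ratio 1.85, 1.32 to 2.40). Fgfr2 had 78.5 and 164 CPM in medulla-like cells, the core of the hair shaft (1.06), and Fgfr1 had 120 and 288 CPM in endothelial-like cells (1.27). Nfatc1, a transcription factor of quiescent bulge stem cells, had 149 and 210 CPM in endothelial-like cells, 66.0 and 66.6 CPM in cluster 20, which held Krt15, Krt6a and Apoe among its leading genes, and 11.7 and 32.8 CPM in dermal papilla-like cells (1.49). The eGFP reporter stood at 2324 and 2800 CPM in cluster 20, 2426 and 5350 CPM in endothelial-like cells, 187 and 411 CPM in T cell or NK cell-like cells, and 142 and 297 CPM in melanocyte-like cells. The tomato sequence of the same reporter had 0 UMIs in both matrices.

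Genes with large ratios of 1 direction in 7 or more classes, such as Wdr89 and Hmgn2, could reflect reads shared between copies, but Neat1, Gadd45g and Hsph1 had no such copy. Of 18 such genes, 7 (38.9%) had a near-identical annotated copy, against 31.1% of 302 other genes of like level, which left this undecided for the genes with a copy. A strain segment linked to Fgf5 was argued against for these genes, since 0 of the 18 lay within 20 Mb of Fgf5, but it stayed open for Spp1 and Epgn, the 2 of 120 named genes of any class that did, at 6.16 and 7.22 Mb. Reads moved between Ftl1-ps1 and Ftl1 stayed open, since the gain of Ftl1 was 0.600 times the loss of Ftl1-ps1 (median over the classes, range -0.04 to 2.22). Genotype, the start of tamoxifen and a difference in how the libraries were read or aligned were not tested.

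The lower share of cluster 0 cells with S phase UMIs (log2 ratio -0.69) could come from how follicle keratinocytes were divided into clusters. Over clusters 0, 2, 6, 10, 18 and 20 together the ratio was -0.13 (-0.23 to -0.04), small beside that in cluster 0, as this explanation predicts. The value cannot decide it, because cluster 2, with S phase shares of 66.1% and 64.0%, gave 383 of 4132 control but 1392 of 3027 mutant cells. A change in the makeup of the pool would shrink the ratio as well. Within the pool, cluster 10 (-0.63) and cluster 20 (-1.18) were also lower, while the intervals of clusters 2, 6 and 18 spanned 0. Free RNA of dividing cells also stayed open, since S phase genes in control cells of cluster 0 were only 1.40 times their highest level in 3 other classes (median of 32 genes, range 0.529 to 7.11). Genotype and the start of tamoxifen were not tested.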
